A study of Homo sapiens with 4 samples.

How the data were processed

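Single-cell 3' gene expression was measured in 4 libraries, 3 batches of multi-tissue organoids (MTO) cultured for 14 weeks and 1 culture of the induced pluripotent stem cell (iPSC) line they were made from. Per the labels' protocols, organoid cells were thawed and passed through dead cell removal before capture, and the same protocol text stands on the iPSC sample. Each library is a matrix of UMI counts per gene and barcode, deposited by the authors as whole numbers without normalization. Per the file headers the matrices were written by Cell Ranger 7.1.0, and per the submitters' processing notes GRCh38.p14, Cell Ranger and Seurat 4.3.0.1 were used, with no roles stated. The annotation version is not given in the sources used here. The feature list held 36601 genes, and gene positions were taken from GENCODE release 29 on GRCh38 by gene identifier.

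The matrices held 5854, 4006 and 12112 barcodes for MTO 1, 2 and 3 and 3019 for iPSC, each with at least 500 UMIs. Barcodes with at least 500 genes and at most 20% mitochondrial UMIs were kept, which were 83.4%, 89.6%, 98.6% and 89.6%. Scrublet, run with exact neighbours, called 0, 2 and 0 MTO cells and 18 iPSC cells, which were removed. With so few calls in MTO, doublets are likely to remain, and why the caller made so few was not tested. Removing the highest scores (0.8% of cells per 1000 cells) was added as an alternative after the data were examined. A first run with approximate neighbours called 0 MTO cells and gave the classes listed for Scrublet calls kept, with no chondrocyte-like cells; exact neighbours replaced it for reproducibility, after the outcome of the first run was known and before that of the exact setting was, and the exact setting was kept. The depth of each library, given with the results, sets the precision, and intervals and floors cover counting error only.

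UMIs were summed per library and tested with edgeR 4.0.16 (quasi-likelihood test, TMM scaling, filter on low counts, Benjamini-Hochberg adjustment at 0.05), 3 MTO batches against 1 iPSC library. Gene lists were tested with camera (correlation preset at 0.01) on voom values in limma 3.58.1, and again with an estimated correlation and with fry. There were 38 lists, 23 of cell type markers (pluripotent, chondrocyte, fibroblast/mesenchymal, osteoblast, tenocyte, neuron, neural progenitor, astroglia, oligodendrocyte, Schwann and neural crest glia, pigment cell, retina, choroid plexus, epithelium, ciliated, endoderm or liver, skeletal, cardiac and smooth muscle, endothelial, immune, erythroid and adipocyte) and 15 of processes. In fry, 14 lists passed in MTO against iPSC, but not the same ones: chondrogenic transcription factors (adjusted p = 0.112 in limma), glycosaminoglycan synthesis (0.0596) and cranial patterning (0.112) did not, while ciliated cell (0.0261), endoderm or liver (0.0276) and smooth muscle or pericyte markers (0.0426) did. Fold changes against 0 UMIs were computed against a floor of 3 UMIs in the iPSC library, and ratios resting on 1 to 3 UMIs carry a counting interval. Where leaving out a batch moved a printed fold over 1.5 times, the fold without it is given. R was version 4.3.3, and DESeq2 1.42.0 served as an alternative.

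MTO cells of the 3 batches were clustered together without batch correction (scanpy 1.11.5, numpy 2.4.6, scipy 1.17.1, python 3.11.15) on 2000 variable genes, 30 principal components, 15 exact neighbours and Leiden resolution 0.8 (leidenalg 0.10.2), leaving out of clustering 475 genes (process lists, mitochondrial, ribosomal protein and Y-linked genes and XIST). A cluster was called like a cell type where at least 3 markers of that list, each detected in at least 10% of its cells, were among its 50 leading genes by mean fold over batches, and more than of any other list, so that a tie stayed unnamed. To compare shares of cells with a UMI, each cell was thinned to 2000 UMIs in 1 random draw for libraries and another for classes, which left out 324, 145, 617 and 404 shallower cells in MTO 1, 2, 3 and iPSC. Class tests used sums of at least 20 cells with the batch as a block, leaving out genes used for clustering. Differences between batches and between classes were taken between sums thinned to one UMI number, over genes with a mean of at least 10 UMIs, with 0.5 UMIs added. The spread between batches was the SD of log2 CPM (0.5 added) over genes with a mean of at least 100 CPM.

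Groups, tests, lists, markers, the rule for named genes and most of the other settings tried were chosen before the data were examined. The rule named POU5F1, NANOG, LIN28A, SOX9, COL2A1 and ACAN always, up to 4 members per list past the threshold by size of change, and the 8 highest and 8 lowest genes with an average log2 CPM of at least 5. In class tests it named up to 4 members per list and the 6 highest and 6 lowest genes with the same direction in every batch. VCAN, SOX5 in the first comparison, OTX2, MKI67, the chondrocyte markers COMP, COL11A1, COL9A1, COL9A2 and MATN1, and the genes of cluster 17 fall outside it or in a figure and were chosen after their values were seen. The planned tests of chondrocyte-like cells could not be run, and tests of neural progenitor-like and tenocyte-like cells were chosen after the data were examined.

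Each test was checked on simulated counts with 200 changed genes. Far more genes passed in the data, 9378 for MTO against iPSC and 2509 for neural progenitor-like cells. The adjusted threshold was therefore stricter in the simulation, and the shares recovered there do not carry over to the data. For MTO against iPSC, with 24672 genes, 0%, 29.9% and 52.2% of genes changed by a log2 of 1, 2 and 3 were recovered, with 7 false calls in edgeR and 56 in DESeq2. Beside 20 and 35 true calls at a log2 of 2 and 3, the 7 make a share above 0.05. For neural progenitor-like cells, with 20190 genes, 33.8%, 78.5% and 100% were recovered, with 86 false calls in edgeR and 0 in DESeq2, so edgeR did not hold its threshold there either. Camera called 2 of 2 changed sets and 0 of 20 unchanged sets.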

Results

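The data were single-cell transcriptomes of 3 batches of multi-tissue organoids (MTO), each cultured for 14 weeks, and of 1 control library of induced pluripotent stem cells (iPSC). All 4 libraries came from ATCC-BYS0110, a commercially supplied human iPSC line, and each UMI counted marks 1 captured transcript. CPM below are a gene's UMIs scaled to a common library total. The labels state that variability between and within organoids and the range of cell types were to be examined, and the title of the series names hyaline cartilage. After filtering, MTO 1, MTO 2 and MTO 3 held 4884, 3589 and 11945 cells, and the iPSC library held 2687 cells. Their UMIs summed to 94201558, 59886926, 67166119 and 18997890. Median UMIs per cell were 17082.5 in MTO 1, 15697 in MTO 2, 4352 in MTO 3 and 6684 in iPSC, so MTO 3 had the most cells and the shallowest ones. The genes followed throughout, with positions in GRCh38 from GENCODE release 29, were POU5F1 (ENSG00000204531, chromosome 6, 31164337 to 31180731, reverse strand), NANOG (ENSG00000111704, chromosome 12, 7787794 to 7799141, forward), LIN28A (ENSG00000131914, chromosome 1, 26410778 to 26429722, forward), SOX9 (ENSG00000125398, chromosome 17, 72121020 to 72126420, forward), COL2A1 (ENSG00000139219, chromosome 12, 47972965 to 48004554, reverse) and ACAN (ENSG00000157766, chromosome 15, 88803442 to 88875354, forward). Nothing in the labels says how far apart the batches were grown, so the spread between them may be partly technical.

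The first comparison asked how the organoids differed from the iPSC line. All 13 pluripotency markers tested were lower in MTO. POU5F1, a core transcription factor of pluripotency, stood at 1.42, 0.0835 and 1.56 CPM in MTO 1, 2 and 3 and at 1024 in iPSC, 1001-fold lower on average (log2 fold change -10.11, SE 1.06, edgeR adjusted p = 0.00185, n = 3 against 1). NANOG was 148-fold lower and LIN28A 1107-fold lower, and the pluripotency-associated transcripts ESRG and MIR302CHG were 4491-fold and 2520-fold lower. MTO 3 held most of the few UMIs of ESRG and MIR302CHG, and without it they were 12036-fold and 8032-fold lower. Adjusted over the list alone, 13 of 13 were lower (camera in limma, adjusted p = 9.94e-13, and adjusted p = 0.485 with an estimated correlation). All 18 proliferation genes were lower as well, 18 of 18 adjusted over the list alone (camera in limma, adjusted p = 1.19e-12, and adjusted p = 0.494 with an estimated correlation). Among them RRM2, needed for nucleotide synthesis, was 30.1-fold lower, and the replication licensing factor MCM5 was 25.3-fold lower. MKI67 stood at 6.85, 4.19 and 13.2 CPM in the MTO batches and at 72.4 in iPSC.

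Genes of connective tissue were the counterpart. All 13 fibroblast and mesenchymal markers were higher in MTO, 13 of 13 adjusted over the list alone (camera in limma, adjusted p = 7.40e-09, and adjusted p = 0.494 with an estimated correlation). COL1A1, the main chain of collagen I, stood at 2193, 2473 and 3771 CPM in the batches and at 24.3 in iPSC, 116-fold higher (log2 fold change 6.72, SE 0.62, edgeR adjusted p = 0.00139). LUM, encoding the small proteoglycan lumican, had 0 UMIs in iPSC and was at least 2687-fold higher, against a floor of 3 UMIs in that library. PRRX1, a transcription factor of limb and craniofacial mesenchyme, was at least 1907-fold higher against the same floor. Of 12 genes of fibrous and fibrocartilage matrix, 10 were higher and none lower, and 10 also when adjusted over the list alone (camera in limma, adjusted p = 2.32e-07, and adjusted p = 0.494 with an estimated correlation). TNC was 244-fold higher in this group, and VCAN, at 261 CPM on average in MTO and 187 in iPSC, did not pass. Of 16 matrix proteases and inhibitors, 11 were higher and 1 lower, the same numbers when adjusted over the list alone (camera in limma, adjusted p = 6.19e-05, and adjusted p = 0.494 with an estimated correlation). The collagenase MMP1 was at least 2315-fold higher, and the membrane protease MMP14 was 81.4-fold higher.

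**Figure D1:**
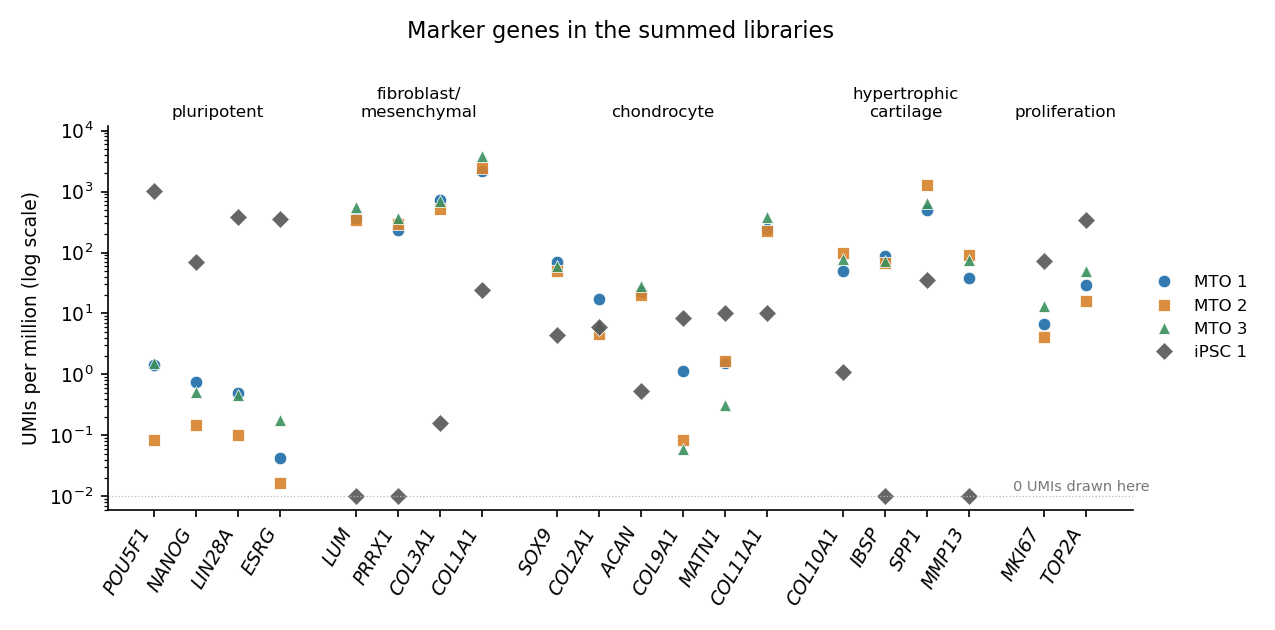
CPM of 20 marker genes (log scale) in the summed cells of MTO 1, MTO 2, MTO 3 and iPSC 1, 1 symbol per library and no error bars. Genes with 0 UMIs are drawn on the dotted line at 0.01. POU5F1 stood at 1.56 or less in every MTO batch and 1024 in iPSC, and COL2A1 at 17.3, 4.53 and 6.43 in MTO and 5.95 in iPSC.

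Cartilage genes were divided. SOX9, the transcription factor that directs chondrocyte formation, stood at 68.8, 49.1 and 61.0 CPM in MTO 1, 2 and 3 and at 4.42 in iPSC, 13.5-fold higher (log2 fold change 3.59, SE 0.32, edgeR adjusted p = 0.00132). ACAN, encoding the cartilage proteoglycan aggrecan, stood at 22.8, 20.3 and 27.8 against 0.526, 45.0-fold higher (log2 fold change 5.34, SE 0.47, edgeR adjusted p = 0.00129). COL2A1, the defining collagen of hyaline cartilage, stood at 17.3, 4.53 and 6.43 CPM against 5.95 and did not pass the test (log2 fold change 0.47, SE 0.72, edgeR adjusted p = 0.632). Without MTO 1 the direction turned, with a mean of 5.48 CPM in MTO, 0.921 times the level in iPSC. Sums over a library do not show which cells made a transcript. Among the clusters described below, SOX9 was highest in neural progenitor-like cells of MTO 1 and MTO 2 and in chondrocyte-like cells of MTO 3. COL2A1 was highest in cluster 17 of MTO 1 and in neural progenitor-like cells of MTO 2 and MTO 3. Clusters were ranked by the lower bounds of their intervals. Of the 20 chondrocyte markers, 7 were higher (MIA, EPYC, ACAN, COMP, COL11A1, COL9A2 and SOX9), 4 were lower (CNMD, UCMA, COL9A1 and MATN1), and 9 did not pass. Adjusted over the list alone, 8 were higher and 4 lower, and the set as a whole did not pass camera (limma, adjusted p = 0.265). COL11A1 stood at 239, 222 and 377 CPM in MTO and 10.2 in iPSC, while CNMD, encoding the cartilage protein chondromodulin, stood at 3.31, 0.568 and 0.476 in MTO and 118 in iPSC.

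Genes of hypertrophic cartilage were higher, 8 of 10, with 1 lower, and 9 higher and 1 lower adjusted over the list alone (camera in limma, adjusted p = 0.00146, and adjusted p = 0.485 with an estimated correlation). COL10A1, the collagen of hypertrophic chondrocytes, was 67.6-fold higher, and IBSP, encoding bone sialoprotein, was at least 482-fold higher against a floor of 3 UMIs. ALPL, encoding the phosphatase needed for mineralization, was 57.6-fold lower in MTO. That ratio depends on the level in iPSC as well and does not show a lack of mineralization in MTO. Of 10 chondrogenic transcription factors, 7 were higher and 1 lower, the same adjusted over the list alone (camera in limma, adjusted p = 0.0489, and adjusted p = 0.494 with an estimated correlation). SOX6, a partner of SOX9, was 15.4-fold higher, and SOX5 at 78.3 CPM on average in MTO and 38.1 in iPSC did not pass. Of 10 genes of articular and superficial cartilage, 5 were higher, including CREB5 (30.8-fold) and PRG4, with 5 adjusted over the list alone (camera in limma, adjusted p = 0.0489, and adjusted p = 0.494 with an estimated correlation). PRG4, encoding the joint lubricant lubricin, rested on 2 UMIs in iPSC, a ratio of 29.04 with a counting interval of 8.04 to 240. Apart from an estimated correlation, and fry for the transcription factors (limma, adjusted p = 0.112), both of these lists lost their call under 6 other settings each, leaving out MTO 1 among them, with camera adjusted p between 0.0501 and 0.0698 in limma. Of 18 genes of glycosaminoglycan synthesis and sulphation, 10 were higher and 1 lower, the same adjusted over the list alone (camera in limma, adjusted p = 0.00915, and adjusted p = 0.494 with an estimated correlation and 0.0596 in fry). CSGALNACT1, which starts chondroitin chains, was 47.1-fold higher, and the hyaluronan synthase HAS3 was 20.2-fold lower.

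Signalling and positional genes followed. Of 18 BMP and TGF-beta ligands and antagonists, 12 were higher and none lower, 12 adjusted over the list alone (camera in limma, adjusted p = 0.00208, and adjusted p = 0.485 with an estimated correlation). INHBA, a subunit of activin A, was 144-fold higher. Of 18 HOX genes tested, 9 were higher and none lower, and 14 adjusted over the list alone (camera in limma, adjusted p = 0.00223, and adjusted p = 0.485 with an estimated correlation). HOXB3 had 0 UMIs in iPSC and stood at 4.06, 2.89 and 11.6 CPM in MTO, at least 39.1-fold higher, or at least 22.0-fold without MTO 3. Of 18 cranial and neural crest patterning genes, 10 were higher and 2 lower, the same adjusted over the list alone (camera in limma, adjusted p = 0.0201, and adjusted p = 0.542 with an estimated correlation and 0.112 in fry). TFAP2B, a neural crest transcription factor, was at least 83.4-fold higher, and OTX2, a forebrain transcription factor, was lower (1.38 CPM on average in MTO and 10.7 in iPSC).

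Stress-related genes also differed. All 14 immediate-early genes, which are known to respond to tissue dissociation, were higher, 14 of 14 adjusted over the list alone (camera in limma, adjusted p = 5.53e-09, and adjusted p = 0.494 with an estimated correlation). FOS stood at 731, 920 and 929 CPM in MTO and 6.11 in iPSC, and the labels state that the organoid cells were thawed and passed through a dead cell removal kit. The same protocol text stands on the iPSC sample, so the labels give no difference in handling. Whether handling played a part was not tested. Of 16 WNT ligands and antagonists 9 were higher and 2 lower (adjusted over the list alone, 9 and 2), of 20 hypoxia and glycolysis genes 5 and 1 (adjusted over the list alone, 5 and 1), and of 14 heat-shock and unfolded-protein genes 3 and 1 (adjusted over the list alone, 3 and 1). Among 13 mitochondrially encoded genes 2 were higher and 1 lower, and adjusted over the list alone 2 and 0. None of these 4 sets passed camera in limma, with adjusted p of 0.172, 0.0653, 0.170 and 0.426 in that order. DKK1, a WNT antagonist, was at least 106-fold higher, and NDRG1, a hypoxia-induced gene, was 263-fold higher.

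Markers of other cell types moved in both directions. Of 11 epithelial markers, 7 were lower and 2 higher, the same adjusted over the list alone (camera in limma, adjusted p = 0.00133, and adjusted p = 0.485 with an estimated correlation). EPCAM, which pluripotent cells also express, was 253-fold lower. Of 14 neuronal markers 2 were higher and 6 lower, and 4 and 8 adjusted over the list alone (camera in limma, adjusted p = 0.0588). SNAP25, a synaptic protein, was 73.4-fold higher. Of 12 neural progenitor markers 2 were higher and 3 lower, of 9 Schwann and neural crest glia markers 2 and 2, and adjusted over the list alone these numbers were the same (camera in limma, adjusted p = 0.324 and 0.396). Of 9 astroglial markers 1 was higher and 1 lower (adjusted over the list alone, 1 and 0), and of 6 oligodendrocyte markers 1 and 1 (adjusted over the list alone, 2 and 1; camera in limma, adjusted p = 0.965 and 0.857). Osteoblast markers were higher in 3 of 7 and tenocyte markers in 2 of 6, with none lower, and in 5 and 3 adjusted over the list alone (camera in limma, adjusted p = 0.0539 and 0.134). DMP1, made by osteocytes, was at least 48.3-fold higher, and SCX, the transcription factor of tendon progenitors, was 8.57-fold higher.

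Among the remaining lists, adipocyte markers were higher in 4 of 5, pigment cell markers in 5 of 8, ciliated cell markers in 3 of 8 and smooth muscle or pericyte markers in 3 of 9, with none lower and the same numbers adjusted over the list alone. Their camera adjusted p in limma were 0.134, 0.0753, 0.148 and 0.172. Retinal markers were higher in 2 of 8 (2 adjusted over the list alone) and choroid plexus markers in 2 of 8 (5 adjusted over the list alone), with none lower and camera adjusted p of 0.285 and 0.148 in limma. Skeletal muscle markers were higher in 3 and lower in 2 of 8, cardiac markers lower in 2 of 5, endothelial markers higher in 1 and lower in 2 of 9, immune markers higher in 3 and lower in 1 of 6, and endoderm or liver markers higher in 2 and lower in 3 of 8. Adjusted over the list alone these numbers were the same, and their camera adjusted p in limma were 0.932, 0.470, 0.481, 0.406 and 0.507. Only 2 erythroid markers had enough UMIs and neither passed, so that list was not tested as a set. MITF, the pigment cell regulator, was 26.6-fold higher, and the pericyte receptor PDGFRB was 67.3-fold higher.

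Across all genes, 9378 of 25276 tested passed an adjusted p of 0.05 in edgeR, 4983 higher and 4395 lower in MTO. Among genes at an average log2 CPM of 5 or more, the 8 with the highest fold changes were FABP4, LUM, MMP1, PRRX1, NNMT, LINC02392, CHRNA1 and IBSP, each with 0 UMIs in iPSC. FABP4, a fatty acid carrier of adipocytes and some endothelium, stood at 739, 2515 and 344 CPM in MTO 1, 2 and 3 and was at least 7597-fold higher, or at least 3431-fold without MTO 2. The 8 lowest were MT1H, ESRG, MIR302CHG, MT1G, TDGF1, LINC00678, LIN28A and POU5F1; the metallothioneins MT1H and MT1G share near-identical sequence with other copies, so their levels are uncertain. With 1 iPSC library, the test assumed that this library varied as the MTO batches did, on 2 residual degrees of freedom. No set passed with an estimated correlation between genes, so the set calls rest on camera with the preset correlation of 0.01. For some sets the estimate was above 0.01, as for proliferation (0.496) and pluripotency (0.0482). For others it was below, as for hypertrophic cartilage (-0.0432), BMP and TGF-beta (-0.0508) and HOX genes (-0.0495), and their calls were lost all the same. For these sets the loss does not show that the call depended on correlation between genes. The estimates had only the 2 residual degrees of freedom of the fit behind them, and every call was lost whatever the estimate. For the other sets, too, the loss therefore cannot tell whether the call depended on correlation between genes.

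The share of cells with at least 1 UMI of a gene gave the same contrast by cell. At 2000 UMIs per cell, POU5F1 was seen in 0.263% of MTO 1 cells (95% exact interval 0.136 to 0.459), 0 of 3444 MTO 2 cells, which allows up to 0.0871% with a UMI at this depth but sets no limit on cells that make it, 0.185% of MTO 3 cells (0.115 to 0.283) and 85.6% of iPSC cells (84.1 to 87.0). Without thinning these shares were 0.758%, 0.139%, 0.360% and 92.9%. Shares by class come from a second random draw of UMIs, so they do not add up to those of the libraries; in it POU5F1 was seen in 2 of 3384 unnamed MTO 2 cells. In the neural progenitor-like cells of MTO 1 described below, which should lack POU5F1, it was seen in 0 of 1172 cells, which allows up to 0.256%, at a median depth of 14706 UMIs against 18110.5 in all MTO 1 cells thinned. TOP2A, made in dividing cells, was seen in 2.24%, 1.34% and 4.25% of MTO cells and 41.0% of iPSC cells, and MKI67 in 0.833%, 0.581%, 1.72% and 12.8%. Unthinned, TOP2A was seen in 6.96%, 4.99%, 6.73% and 66.9%, and MKI67 in 2.09%, 1.53%, 3.61% and 35.3%. Cluster 12, described below, had the highest levels, with TOP2A at 976 CPM and MKI67 at 250.1, against at most 60.7 and 12.6 in any other cluster. In the second draw, TOP2A was seen in MTO 1 in 1.45% of neural progenitor-like cells and 2.14% of unnamed cells, at median depths of 14706 and 19743 UMIs. NANOG was seen in 0.132%, 0.0290% and 0.115% of MTO cells and 13.8% of iPSC cells, and unthinned in 0.962%, 0.251%, 0.226% and 34.4%.

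The next question was which cell types the organoids held. The 20418 MTO cells fell into 19 clusters, of which 3 clusters with 9.11% of the cells carried at least 3 markers of a fixed cell type list and more of it than of any other list. Cluster 6 was neural progenitor-like (FABP7, PTPRZ1, SOX2 and TTYH1), with the glial genes S100B, PMP2 and CDH19 also among its leading genes. It held 24.8% of MTO 1, 0.9752% of MTO 2 and 0.553% of MTO 3 (mean 8.78% ± 13.9, SD, n = 3), and 0.764% on average without MTO 1. Cluster 15 was chondrocyte-like (EPYC, COL9A3 and MIA) and held 0.123%, 0.279% and 2.23% (mean 0.876% ± 1.17, SD, n = 3), and 0.201% on average without MTO 3. In its MTO 3 cells COL2A1 stood at 7.69 CPM (10 UMIs, 95% exact interval 3.69 to 14.1) and ACAN at 20.8 (27 UMIs, 13.7 to 30.2), against 6.43 and 27.8 in all MTO 3 cells, so neither difference was resolved. SOX9 stood higher there, at 91.5 (119 UMIs, 75.8 to 110) against 61.0. Cells with at least 5 of a set of 16 cartilage genes were most frequent in another batch. Without thinning they numbered 183 of 4884 in MTO 1, 18 of 3589 in MTO 2 and 7 of 11945 in MTO 3. MTO 3 cells were also the shallowest, so these counts and the class share do not settle which batch held more cartilage-type cells. MTO 1 and MTO 2 differed less in depth, with medians of 17082.5 and 15697 UMIs. By the lower bounds of cluster intervals, COL2A1 and SOX9 in MTO 1 were highest in clusters 17 and 6, at 117 and 111 CPM. Cells counted by cartilage genes therefore need not be chondrocytes, and the clusters they fell in are not given here. Cluster 16 was tenocyte-like (TNMD, SCX, FMOD and THBS4) and held 0.143%, 0.446% and 2.03% (mean 0.872% ± 1.01, SD, n = 3), and 0.295% on average without MTO 3.

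The other 16 clusters, with 74.9%, 98.3% and 95.2% of the cells of MTO 1, 2 and 3, stayed unnamed. Cluster 17 had 4 markers each of 2 lists, and the others reached 3 markers of no list. No cluster was fibroblast/mesenchymal-like, although COL1A1 was seen in 72.2%, 75.8% and 92.9% of MTO cells at 2000 UMIs per cell and in 4.205% of iPSC cells, which should lack it, at median depths of 18110.5, 16050.5, 4544 and 7318 UMIs. Unthinned, these shares were 90.5%, 92.6%, 96.3% and 13.0%. In the second draw COL1A1 was also seen in 48.8%, 35.3% and 53.8% of the neural progenitor-like cells of MTO 1, 2 and 3, so a UMI of COL1A1 does not mark a fibroblast here. The batches filled the clusters unequally: cluster 4, led by FABP4 and AREG, held 33.1% of MTO 2 and 4.2998% and 3.53% of the other two. Cluster 1, led by CRABP1 and MMP1, held 26.7% of MTO 3, 9.75% of MTO 2 and 1.80% of MTO 1, and MTO 3 was also the shallowest library. Cluster 12, led by TOP2A and UBE2C, held 1.06%, 0.9752% and 4.29% of MTO 1, 2 and 3; proliferation genes of the fixed list had been left out of the clustering. These names depended on the clustering. With only the 2 MTO cells put back that had been called doublets, the partition shared an adjusted Rand index of 0.567 with the one used here, and no cluster was chondrocyte-like. With each batch clustered alone, a fibroblast/mesenchymal-like cluster did appear, with COL3A1, LUM, PDGFRA, COL1A1 and COL1A2 among its leading genes.

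**Figure D2:**
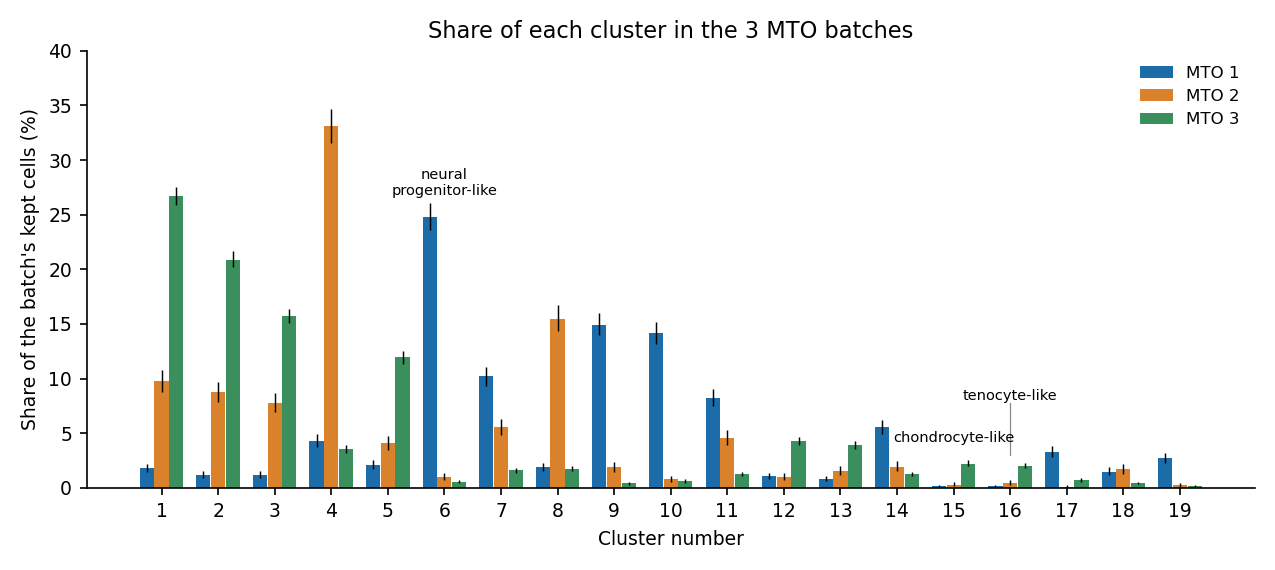
Share of each of the 19 clusters (percent of the batch's kept cells, bars from 0, with exact 95% binomial intervals that cover counting error only) in MTO 1, MTO 2 and MTO 3. Cluster 6, neural progenitor-like, held 24.8% of MTO 1 and under 1% of the other two, while cluster 4 held 33.1% of MTO 2.

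A test of chondrocyte-like cells against all other MTO cells had been planned, as had a test against fibroblast-like cells. Neither could be run, since 20 chondrocyte-like cells were found only in MTO 3 and no cluster was fibroblast-like. In the clusterings with enough cells for a test, these names fell wholly or partly on clusters led by other genes than here, so their counts do not stand in for the planned comparison. With all deposited barcodes, the chondrocyte-like cluster (1576 cells) was led by RDH10, ENPP1, COL10A1 and MMP13. Its name rested on HAPLN1, COL2A1, COL11A1 and MIA, none of them among its first 10 genes. There 1264 of 19120 genes passed in edgeR (652 higher and 612 lower). At a Leiden resolution of 1.4 and at 10% mitochondrial UMIs, the cells so named had EPYC but also the tenocyte markers TNMD and SCX among their first 10 genes, like cluster 16, and 547 and 550 genes passed in edgeR in a pair of batches, on 1 residual degree of freedom. The name rested on EPYC, COL11A1 and ACAN in both. Whether any of these clusters held more cartilage cells than cluster 15 was not tested. Tenocyte-like cells, tested after the data were seen, gave 2984 to 3825 genes in edgeR in 4 clusterings. At a Leiden resolution of 0.4 and at 10% mitochondrial UMIs those cells were led by FABP4 and AREG, as was one of the tenocyte-like clusters with all deposited barcodes, and none of these had a tenocyte marker among its first 10 genes. With Scrublet calls kept they were led by CADM2, like cluster 7.

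Neural progenitor-like cells were the one class with 20 cells in every batch, and their test was chosen after the data were seen. Its fit had 2 residual and infinite prior degrees of freedom, so each gene's variance was taken from a value shared over genes. The SE and edgeR adjusted p of single genes in this test therefore do not measure that gene's own spread between batches. Compared with all other cells of the same batch, they had more PANTR1, a noncoding RNA of the developing brain (286, 218 and 359 CPM in MTO 1, 2 and 3 against 23.0, 9.57 and 13.7), and more CLU, encoding clusterin (log2 fold change 3.45, SE 0.21, edgeR adjusted p = 1.34e-59). EN2, a midbrain and hindbrain transcription factor, MLC1, ADGRG1 and NRCAM were the other highest genes. The 6 lowest were MMP13, MMP1, RFX8, SEMA7A, FOXD1 and CTSK. MMP13 stood at 4.37 CPM in these MTO 1 cells against 48.6 in the other MTO 1 cells, with 0 UMIs in those of MTO 2 and MTO 3. TIMP3 was lower (log2 fold change -2.66, SE 0.20, edgeR adjusted p = 3.39e-36), and the hypertrophic cartilage gene SPP1 stood at 88.3, 345 and 213 CPM against 626, 1278 and 657.

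In this test 6 lists were lower in camera of limma: hypertrophic cartilage (adjusted p = 0.0295), fibrous matrix (0.0203), matrix proteases and inhibitors (1.06e-04), proliferation (1.62e-07), hypoxia and glycolysis (0.0203) and heat-shock and unfolded-protein genes (0.0348). With an estimated correlation their adjusted p were 0.598, 0.615, 0.598, 0.598, 0.691 and 0.691. This fit also had 2 residual degrees of freedom, so the loss cannot tell whether these calls depended on correlation between genes. The proliferation result was favoured by the partition, since the dividing cells of cluster 12 are in the comparison group, and is not taken as a property of these cells. Cluster 2, with MMP11, MMP13, IBSP, COL10A1 and TIMP3 among its first 10 genes, is in that group too. The hypertrophic cartilage and matrix protease results therefore carry the same limit. The test was not repeated without these clusters. Of 15 matrix protease genes not used for clustering, 8 were lower and 1 higher (10 and 1 adjusted over the list alone), and of 18 proliferation genes 10 were lower (12 lower and 1 higher adjusted over the list alone). Of 10 hypertrophic cartilage genes 5 were lower and 2 higher (6 and 2 adjusted over the list alone), of 6 fibrous matrix genes 3 were lower (5 adjusted over the list alone), and of 20 hypoxia genes 5 were lower (5 lower and 1 higher adjusted over the list alone). Of 14 heat-shock and unfolded-protein genes 3 were lower and 1 higher (5 and 1 adjusted over the list alone). The other 9 lists did not pass camera. Of the 9 chondrogenic transcription factors left, 3 were higher and 4 lower, also adjusted over the list alone, and SOX5 was higher (log2 fold change 1.90, SE 0.19, edgeR adjusted p = 7.05e-21). HOX genes were higher in 1 and lower in 7 of 13, and glycosaminoglycan genes higher in 3 and lower in 3 of 18, the same adjusted over the list alone, as were articular cartilage genes (1 and 2 of 9) and mitochondrially encoded genes (0 and 0 of 13). BMP and TGF-beta genes were higher in 4 and lower in 6 of 18 (5 and 7 adjusted over the list alone), WNT genes in 4 and 4 of 14 (4 and 6), cranial patterning genes in 3 and 4 of 14 (3 and 6), and immediate-early genes in 0 and 4 of 14 (1 and 5). For genes changed, neural progenitor-like against all other MTO cells, 2509 of 19602 genes not used for clustering passed in edgeR, 1024 higher and 1485 lower, with the batch as a block. The class sums of MTO 2 and MTO 3 rested on 35 and 66 cells, without MTO 1 the count was 1163, without the batch block 1533, and with DESeq2 1389. On simulated data this test also called 86 unchanged genes of 20190 genes run, so the threshold was not held there and the count holds an unknown number of false calls. The class was cut from these same cells by expression, so a high count was favoured in advance, also among genes not used for clustering.

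Differences between batches within a cell type were to be set against differences between cell types. No named class had 50 cells in every batch, so the named classes gave no value. Over the 10 clusters with 50 cells in every batch, the same cluster in different batches differed by a median absolute log2 ratio across genes of 0.361 ± 0.0261 (mean and SD over 30 pairs), and different clusters of the same batch by 0.708 ± 0.413 (135 pairs), each sum thinned to 157687 UMIs. The clusters were cut from these same cells by similarity without batch correction, so a larger difference between clusters than between batches was favoured in advance. Clusters held mostly by MTO 1, such as 6, 9 and 10, lacked 50 cells in another batch and dropped out. The kept clusters include cluster 11, with a median of 1972 UMIs per cell and 7.44% mitochondrial UMIs. Random splits of 1 sum into equal parts differed by 0.274, the level that counting noise alone gives. Other settings compared other things, with the unnamed cells pooled as 1 class and sums of other sizes, so they do not test this contrast. At a Leiden resolution of 0.4 (2 classes) the values were 0.317 between batches, 0.301 between classes and 0.139 for random splits, and with 3000 variable genes (3 classes) 0.336, 0.362 and 0.248. Pairs share sums and are not independent, so no test was made.

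The 8 genes with the largest spread between MTO batches, among 1489 genes with a mean of at least 100 CPM, were DLK1, CLU, CRYAB, FABP4, MMP11, PTN, ANGPTL4 and AREG. Their SDs of log2 CPM lay between 1.18 and 1.73, where the median of all these genes was 0.182. DLK1, a noncanonical Notch ligand, stood at 505, 137 and 45.9 CPM in MTO 1, 2 and 3, and CLU at 793, 89.4 and 118. FABP4 and AREG, an EGF receptor ligand, were highest in MTO 2, at 2515 and 564 CPM. MMP11, a matrix protease, was highest in MTO 3, at 549 against 86.4 in MTO 1 and 303 in MTO 2. With 3 batches the ranking rested on single libraries: 2 of the 8 genes stayed among the 8 without MTO 1, 4 without MTO 2 and 5 without MTO 3.

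Cluster 17, defined in part by POU5F1, held 160 cells of MTO 1, 4 of MTO 2 and 83 of MTO 3. The batches differed in what it held. In MTO 1, the cluster's summed cells carried POU5F1 at 4.82% of the level in iPSC (95% exact interval 4.005 to 5.75), NANOG at 27.6% (20.3 to 36.8), LIN28A at 2.05% (1.25 to 3.17), TDGF1 at 1.87% (1.02 to 3.13) and ESRG at 0.112% (0.00283 to 0.623). In MTO 3 these were 29.7% (24.0 to 36.4), 107.7% (68.0 to 162), 20.04% (12.8 to 29.8), 19.5% (11.6 to 30.9) and 10.0% (4.99 to 17.9), with 23 UMIs of NANOG and 11 of ESRG. SOX2, which neural cells share, stood at 88.6% (80.8 to 97.0) and 46.3% (32.1 to 64.9). At 2000 UMIs per cell, POU5F1 was seen in 8 of 148 cluster cells of MTO 1 and 20 of 61 of MTO 3, and PTPRZ1 in 42 and 15, so most cells of the cluster showed no POU5F1 at that depth. In MTO 1 a single cell held 45 of the cluster's 124 POU5F1 UMIs. At least 2 of 8 pluripotency genes were seen in 21 of the 160 cluster cells of MTO 1 and 27 of the 83 of MTO 3. The cluster had 4 pluripotency and 4 neural progenitor markers among its leading genes and stayed unnamed. In other clusterings a cluster with POU5F1 and DPPA4 among its first 10 genes was named pluripotent-like. These were the runs with 3000 variable genes, with all deposited barcodes and at 10% mitochondrial UMIs. Since pluripotency genes defined cluster 17, their presence is no finding, and the values describe how far each lay from the iPSC library.

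**Figure D3:**
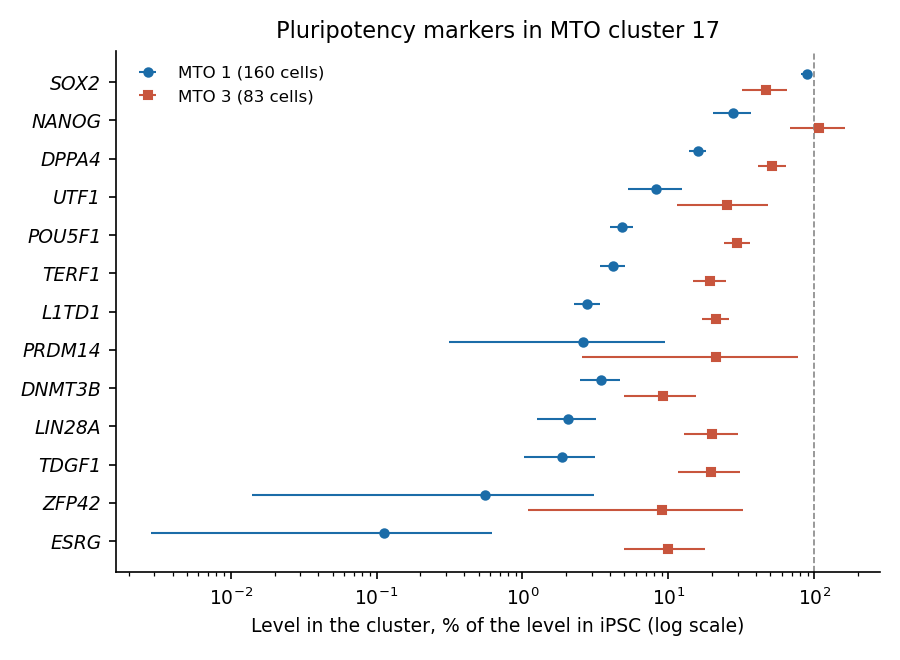
Level of 13 pluripotency markers in the summed cells of cluster 17, as a percentage of the level in the iPSC library (log axis, exact 95% intervals that cover counting error only, dashed line at 100%), circles for 160 cells of MTO 1 and squares for 83 cells of MTO 3. The 4 cells of MTO 2 are not drawn. ESRG stood at 0.112% in MTO 1 and 10.0% in MTO 3, and POU5F1 at 4.82% and 29.7%.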

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

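Values for neural progenitor-like cells and for the highest doublet scores removed come from tests chosen after the data were seen. The count of 9378 genes for MTO against iPSC stayed within 1.5 times, from 6890 without MTO 2 to 10905 without MTO 1. Of 137 named genes none changed direction with a pass in either run, and 126 kept their side of the threshold under every alternative run. COL2A1, which did not pass, turned to 0.921 times the iPSC level in mean CPM without MTO 1. Of 14 lists that passed camera, 12 did so in every alternative except estimated correlation, where 0 passed, and fry, where 11 did. No paired analysis was possible because MTO and iPSC share fewer than 2 replicate numbers. For genes changed, neural progenitor-like against all other MTO cells, 2509 became 1533 with no replicate block, 1389 in DESeq2 with batch, 1640 at Leiden resolution 1.4, 1320 with 3000 variable genes, 1137 with each batch clustered alone, and 1163 (without MTO 1) to 2142 without a batch; the cause was not tested, but with 3000 variable genes the name covered a MEPE-led cluster, and in batches alone it missed an OTOR-led cluster and took in a POU5F1-expressing one. Its 6 lists became 0 with estimated correlation and 0 in fry. The mean share of chondrocyte-like cells, 0.876%, became 5.66% with all deposited barcodes. There the name fell on a cluster led by other genes, with HAPLN1, COL2A1, COL11A1 and MIA as its markers. The share was 0% at Leiden resolution 0.4, with Scrublet calls kept and with the highest doublet scores removed. That of tenocyte-like cells, 0.872%, became 21.9% at Leiden resolution 0.4, 14.0% with all deposited barcodes, 17.1% at 10% mitochondrial UMIs, 6.75% with Scrublet calls kept and 2.43% with each batch clustered alone, and 0% at Leiden resolution 1.4. With Scrublet calls kept the name covered CADM2-led cells, at Leiden resolution 0.4 and 10% mitochondrial UMIs FABP4-led cells, and with all barcodes and batches alone both FABP4-led and TNMD-led cells, so these are not shares of one population. That of neural progenitor-like cells, 8.78%, was 0% at Leiden resolution 0.4 and with all deposited barcodes, where clusters with OTOR, FABP7 and PTPRZ1 among their first 10 genes tied between lists and lost the name, and 0.956% with each batch clustered alone. The mean share of cells with a POU5F1 UMI, MTO batches at 0.1495%, became 0.419% unthinned, 0.0927% without MTO 1 and 0.224% without MTO 2, and that with a TOP2A UMI, 2.61%, became 6.23% unthinned, since deeper cells show more genes. Of the 8 genes with the largest spread, 0 stayed among the 8 at a mean of at least 20 CPM, which admits other genes, and 2 to 5 without a batch. Other settings chosen in advance for the chondrocyte-like tests gave no value beyond those reported, and the differences between batches and classes gave none at Leiden resolution 1.4, with each batch clustered alone, with other minimum counts, or without MTO 1 or MTO 3.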

Other observations

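COL2A1 and ACAN were highest in different clusters, which were looked up after the data were seen and ranked by the lower bound of each cluster's interval. COL2A1 stood at 25.4, 32.4 and 104 CPM in the neural progenitor-like cells of MTO 1, 2 and 3, where ACAN stood at 3.98, 2.32 and 0. In MTO 1, COL2A1 was highest in cluster 17, at 117 (95% exact interval 104 to 131), where at 2000 UMIs per cell 8 of 148 cells had a POU5F1 UMI and 42 one of PTPRZ1. ACAN was highest in clusters 9, 1 and 16 of MTO 1, 2 and 3, at 67.5, 55.8 and 84.2, and SOX9 was highest in the neural progenitor-like cells of MTO 1 and MTO 2, at 111 and 107, and in the chondrocyte-like cells of MTO 3, at 91.5, where SOX9 in clusters 19 and 6 stood at 137 on 14 UMIs and at 104 on 20. FABP4 was abundant in clusters 4 and 7 of every batch, from 4060 to 8249 CPM, and these clusters held 4.2998% and 10.2% of MTO 1, 33.1% and 5.54% of MTO 2, and 3.53% and 1.62% of MTO 3.

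All tests of the explanations below were chosen after the result was seen, and the clusters themselves depend on the clustering. The first pattern is the POU5F1-expressing cluster in MTO. Barcode swapping with the iPSC library would put its barcodes in that library, and 0.405% of them were there. Unchanged iPSC would hold POU5F1, NANOG, LIN28A, TDGF1 and ESRG at one percentage of their iPSC level, but NANOG stood 247 times as high as ESRG on that scale in MTO 1 (32.5 times by the bounds of their intervals) and 10.8 times in MTO 3 (3.8001 by the bounds). In MTO 3 this rests on NANOG alone, with 23 UMIs. The bounds treat UMIs as independent, although UMIs can gather in single cells, as those of POU5F1 did in MTO 1. NANOG and ESRG were also picked as the highest and lowest of these genes. The ratios by the bounds may therefore be too high, and the small one of MTO 3 is the least secure. The test concerns unchanged iPSC as the only carriers; some unchanged iPSC, up to the 0.623% of the cluster's UMIs in MTO 1 and 17.9% in MTO 3 that the bounds of ESRG allow, stay open. The 4 cells of MTO 2 were too few to test, and no biological explanation was tested.

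The second pattern is the COL2A1 level in MTO, which did not pass the test against iPSC. It stood at 17.3 CPM in MTO 1 (16.5 to 18.2), 4.53 in MTO 2 and 6.43 in MTO 3, against 5.95 (4.90 to 7.15) in iPSC, so MTO 1 lay above beyond counting error. These intervals do not cover variation between libraries. The cell filter did not remove it, since the CPM of COL2A1 over all barcodes was at most 1.00 times that over kept cells. Free RNA spread over all cells would give one level in every cluster, but the highest cluster's lower bound was at least 14.9 times the lowest cluster's upper bound in every batch. Capture of this transcript by the 3' assay, and loss of matrix-embedded cells on dissociation, were not tested and stay open.

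The third pattern is the level of glial genes in MTO 1. Depth would bring the batches together at one UMI number per cell, but the share of cells with an S100B UMI at 2000 UMIs stayed 12.8 times that of the next batch. Clustering and naming play no part in the UMI sum, where FABP7 was 28.7 times as high as in the next batch. Handling that differed between batches stays open, and no biological explanation was tested, since the batches are replicates of 1 group.

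For neural progenitor-like cells against all other MTO cells, 1 of the 10 splits of the 6 sums, the real one, gave as many as 2509 genes, and the highest other gave 94. Of these, 4 splits part the paired sums of every batch as the real one does, and the highest other among those gave 0. With 10 splits a share under 0.05 cannot be reached. The real split was also cut from these same cells by expression, so a higher count for it was favoured in advance. Leaving out the genes used for clustering does not remove this, since other genes can follow the same partition. The splits therefore do not test the 2509 genes.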
